A study of Sus scrofa with 3 samples.

How the data were processed

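RNA from 3 pig cell cultures was measured on 3 Affymetrix Porcine Genome arrays, 1 array per culture. Per the labels, 2 cultures (pESK I and pESK II) are lines derived from the inner cell mass of blastocysts produced in vitro and carry lentiviral human KLF4 and the M2rtTA activator, and the other (pUC) is a primary umbilical cord culture. Per the labels' protocols, 10 µg of total RNA per sample was labelled with biotin by the maker's in vitro transcription kit. The authors deposited a table of 24123 probe set values per array, and these deposited values are intensities on a linear scale. The summarisation method and the scaling are not given in the sources used here. The mean intensity after trimming 2% at each end was 500.1 on each of the 3 arrays, so the values carry a scaling to a common trimmed mean. Scanner files were not used here.

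From these values, 124 array control probe sets were left out, and log2(intensity + 16) was taken without further normalization. The offset damps differences between dim values, so log2 differences of dim genes understate the change. Probe sets entered if the highest of their 3 values reached the median of all values (an intensity of 91.2), which kept 14194 of 23999. Of those 23999, 10069 had 1 gene symbol in the platform annotation, 198 had several and 13732 had none. The Entrez identifiers of 9961 of the 10069 were found in a RefSeq gene table of the pig, and symbols were kept as the annotation gives them. Where a gene had several passing probe sets, which held for 1368 genes, the probe set with the highest mean over the 3 arrays was used. In 10 genes the probe sets went opposite ways by the rule of size below. This left 5222 genes.

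Background was bounded by 59 bacterial control probe sets without signal, whose highest intensity was 22.1 on the pESK I array, 23.5 on the pESK II array and 18.3 on the pUC array. A probe set at or below that level has only an upper bound there. Folds are ratios of intensities, taken for whichever pESK line lay closer to pUC, and where the dimmer value was at or below the bound it was replaced by the bound and the fold is written as "at least". Each group is 1 array, so the number of arrays limits the precision, and no spread within a group can be measured. Sequencing depth does not apply to arrays.

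The comparisons were pESK against pUC and pESK I against pESK II. Because no group has a replicate, genes were called by size: a log2 difference of at least 1 against pUC in both lines in the same direction, or of at least 1 between the lines. Lists of genes, 27 in all, were fixed before the data were examined. Some genes are on more than 1 list, so the lists are not independent of each other. Each is described by how many measured members met the rule and by the median log2 difference, set as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A percentile was given only for lists with at least 3 measured genes, which were 23. It describes these arrays and is not a test across samples.

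The rule for named genes, also fixed beforehand, took KLF4, then POU5F1, NANOG and SOX2 where measured. It further took the 12 genes with the largest difference in each direction of each comparison, ranked against pUC by the smaller of the differences of the 2 lines. From each list it took up to 4 measured members with the largest difference, and up to 2 that went the other way by at least 1. The male-linked genes were included as a check of labels.

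The alternatives fixed before the data were examined were quantile normalization, centring of each array on its median, no filter and a filter at the 75th percentile, offsets of 1 and 64, the mean of a gene's probe sets, a 4-fold threshold, each line alone, and limma with the 2 lines taken as replicates of 1 group. The limma alternative used lmFit and eBayes with a trend, 1 residual degree of freedom and an adjusted p threshold of 0.05. Counts over all probe sets, and counts with both pESK values above the controls, were added after the data had been seen.

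The calling rule and limma were tested on simulated data built from the 5222 genes of the comparison with pUC. Noise was drawn from the differences between the 2 lines. It holds no variation between umbilical cord cultures, so the rates below need not hold for the real comparison with pUC. With 50 genes changed at each size, the rule recovered 90% at a log2 change of 1.5, 98% at 2, and 100% at 3 and at 4, and called 0.697% of the 5022 unchanged genes. limma recovered 86%, 96%, 100% and 100%, and called 0.358% of the unchanged genes. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.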

Results

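Expression was profiled in a pair of pig stem cell lines and in pig umbilical cord cells. Both lines, pESK I and pESK II, were grown from the inner cell mass, the part of the blastocyst that forms the embryo proper, and both received human KLF4 by lentivirus. pESK I (passage 14) came from an inner cell mass freed by hand, and pESK II (passage 5) from one freed by immunosurgery, in which antibody and complement lyse the outer cells. The lines were kept on mouse embryonic feeder cells. The reference was a primary umbilical cord culture, pUC, at passage 4, taken at day 34 of pregnancy. It was grown in 10% serum with 4 ng/ml of FGF2. Cell origin, culture conditions and the lentiviral vectors differ together between the lines and pUC and cannot be separated here. Each group is 1 array, so none of the differences below has a replicate check. The median intensity was 82.8 for pESK I, 74.5 for pESK II and 119.9 for pUC, and 69.0%, 66.8% and 76.9% of probe sets lay above the highest control without signal.

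The transduced factor was looked at first. The pig KLF4 probe set was lower in both lines than in pUC, with intensities of 272 in pESK I, 230.5 in pESK II and 1082 in pUC, 3.98-fold lower in the line closer to pUC. The probe set was designed on the pig gene and may not read the human transcript, so this value checks neither the transgene nor the labels. Of the 20 members of the core pluripotency list, only 3 had a probe set named on the array, and 0 passed the filter. The list as a whole was therefore not measured. POU5F1, the gene of OCT4, read 36.3 in pESK I, 13.4 in pESK II and 8.37 in pUC, with only the pESK I value above the controls. DPPA5 read 12.7, 28.3 and 13.7, and ZFP42 read 6.34, 9.84 and 4.15. NANOG and SOX2 were not among the probe sets with a symbol and were not analysed here. As a check of labels, EIF1AY on the Y chromosome read 1259, 1443 and 884.5, while SRY read 13.5 and 6.31 in the lines, below the controls, and 102.5 in pUC. The labels call both pESK lines male and leave the sex of pUC open.

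The first comparison asks how the inner cell mass lines differ from a differentiated culture of the same species. Against umbilical cord cells, both pESK lines had far lower levels of matrix, fibroblast and contractile genes and of interferon and inflammatory genes, and higher levels of cell cycle genes. The genes highest above pUC included FGF13 and FGF12, intracellular members of the fibroblast growth factor family, the former at least 144-fold and the latter 56.0-fold higher. SCRG1 was at least 105-fold higher, PKIB, an inhibitor of protein kinase A, 76.0-fold, and KIF5C, a kinesin motor, 68.5-fold. SATB1, a chromatin organiser, was at least 60.9-fold higher, B3GALNT1 at least 60.2-fold and KLK4 at least 54.1-fold. FAM162B, SCIN, TDH (threonine dehydrogenase) and the endoderm factor FOXA1 completed the 12, at least 47.8-fold, 47.4-fold, 35.7-fold and 32.9-fold higher. The genes farthest below pUC were POSTN, at least 588-fold lower, THBS2 463-fold, ANXA1 431-fold, DCN 425-fold, BGN at least 383-fold and SPP1 at least 367-fold. The folds of THBS2, ANXA1 and DCN rest on pESK I readings of 24.9, 26.4 and 27.9, close to the highest control of 22.1, and are imprecise. CCL2, ASPN, LUM, AEBP1, NPY and COL4A2 were lower by at least 347-fold, 344-fold, 327-fold, 287-fold, 270.5-fold and 268.5-fold.

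**Figure D1:**
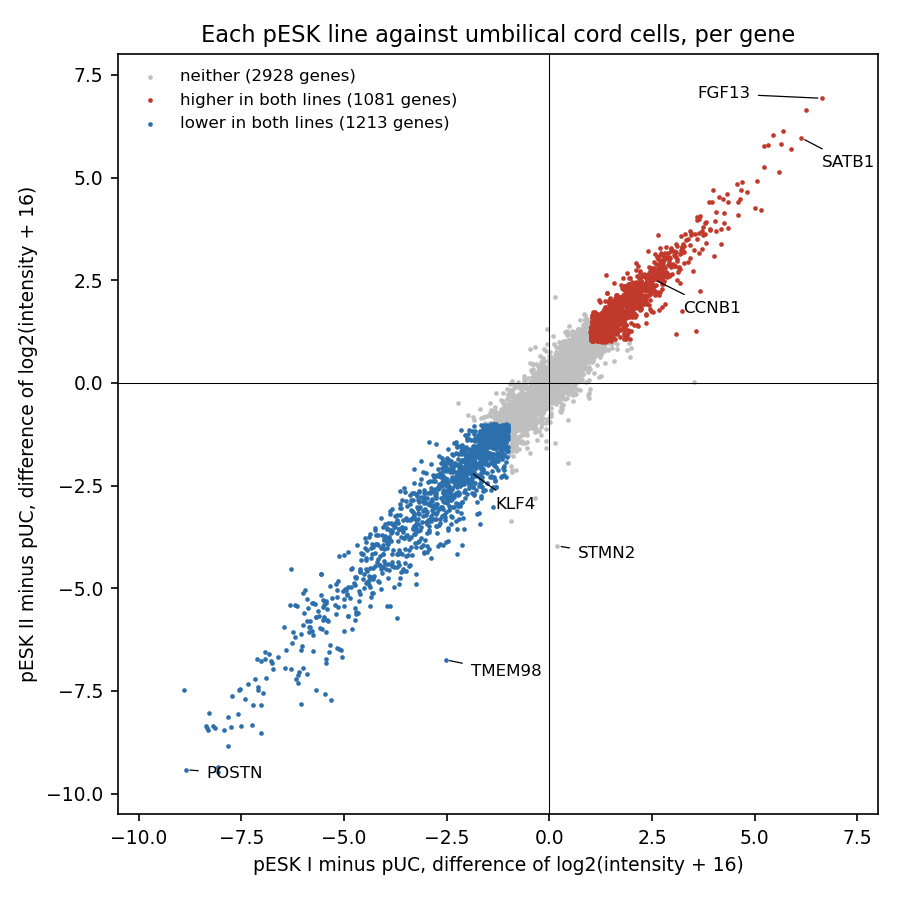
Each point is 1 of 5222 genes, with the difference of log2(intensity + 16) between pESK I and pUC on the horizontal axis and between pESK II and pUC on the vertical axis. The 1081 genes higher in both lines (red) and the 1213 lower in both (blue) lie along the diagonal, and STMN2 and TMEM98 lie far below it.

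The matrix, smooth muscle and mesenchymal lists had the lowest medians of the fixed lists. All 19 measured mesenchymal and fibroblast genes were lower in both lines, with a median log2 difference of -4.64, below each of the 10000 random lists. Beside POSTN, DCN and LUM, THY1, a surface marker of fibroblasts, was 171-fold lower. All 17 fibrillar collagen and matrix genes were lower, with a median of -5.44, among them TNC at least 264-fold, COL15A1 192-fold, THBS2 and BGN. All 10 smooth muscle and contractile genes were lower, with a median of -4.77, including CNN1 by 153-fold, TPM2 by 69.9-fold, DES by 47.8-fold and SMTN by 33.1-fold. Both of these medians also lay below each of the random lists.

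Interferon and inflammatory genes were lower as well. Of 15 interferon response genes, 14 were lower in both lines and 1 met neither rule, with a median of -3.55 at percentile 0.19. MX1 was at least 113-fold lower, ISG15 115-fold, IFIT3 57.4-fold and IFI44L 42.3-fold. Of 13 antigen presentation and inflammatory genes, 12 were lower and 1 met neither rule, with a median of -3.14 at percentile 0.21. The chemokine CCL2 led them, CXCL8 was at least 29.4-fold lower, IL6 at least 26.1-fold, and PTGS2, the inducible cyclooxygenase, 23.0-fold. With the stricter filter 8 genes of each list remained and the percentiles of 15.04 and 20.15 lay inside the middle 95% of random lists.

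Genes of cell division went the other way. Of 19 cell cycle and DNA replication genes, 17 were higher in both lines, 1 was lower and 1 met neither rule, and the median of 2.55 lay above each of the random lists. The replication helicase subunits MCM2 and MCM5 were 16.1-fold and 10.3-fold higher, the replication clamp PCNA 11.7-fold and the mitotic activator CDC20 9.80-fold. The lower gene was the cyclin CCND2, by 2.13-fold. Of 9 genes of CDK inhibitors and p53 targets, 7 were lower and 2 met neither rule, with a median of -2.37 at percentile 0.205. CDKN1A, the gene of p21, was 6.21-fold lower, GADD45A and GADD45B were 9.10-fold and 9.12-fold lower, and PHLDA3 5.24-fold. Without a filter the median of this list was -1.38 over 12 genes.

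Of 21 oxidative phosphorylation genes, 9 were higher, 0 lower and 12 neither, with a median of 1.0 at percentile 96.7, inside the middle 95% of random lists. CYCS, which encodes cytochrome c, was 4.17-fold higher, NDUFS1 2.74-fold, SDHA 2.74-fold and NDUFA9 2.62-fold. Of 16 glycolysis genes, 1 was higher, 3 were lower and 12 met neither rule, with a median of -0.03 at percentile 2.725. The percentile lay outside the middle 95% of random lists in 5 of 9 settings, and the median was 0.49 under median centring, which shifts all genes of an array alike. LDHB was 2.10-fold higher, while ENO2 was at least 23.9-fold lower, ALDOC 5.45-fold and the glucose transporter SLC2A1 3.56-fold. Of 12 housekeeping reference genes, 3 were higher (EEF1A1 by 14.1-fold, HPRT1 by 4.19-fold and SDHA). A further 1 was lower (GUSB, 2.62-fold) and 8 met neither rule, with a list median of 0.31. The EEF1A1 fold is that of 1 of its 3 passing probe sets, which read 191.7 in pUC.

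**Figure D2:**
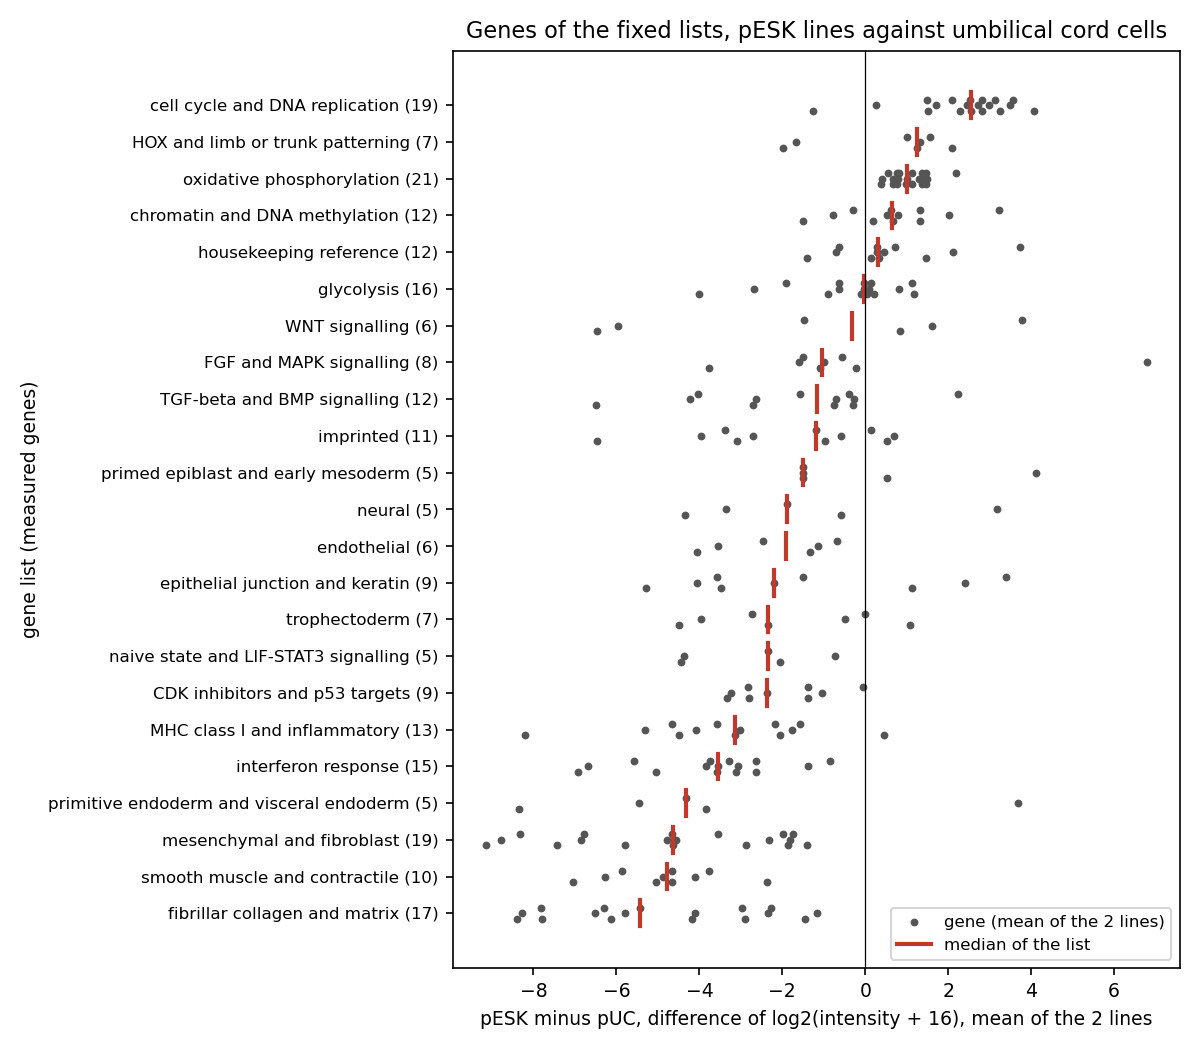
Each point is a measured gene of a fixed list with at least 5 measured genes, placed by the mean over the 2 lines of its difference in log2(intensity + 16) from pUC; red bars are list medians and the number of genes is in brackets. The cell cycle list has the highest median (2.55) and the matrix list the lowest (-5.44).

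Of the markers of embryonic lineages that passed the filter, most were lower in both lines than in pUC and few were higher. Several, among them GATA6, NR5A2, MYC and HAND1, passed through the pUC value alone and lay at or below the controls in both lines. POU3F1 and RBP4 passed through the lines, with pUC at 2.17 and 40.1. GATA4, FOXA2 and TFAP2C were dim on all 3 arrays and did not enter. The counts therefore depend on which markers were bright in pUC. In the primitive endoderm list, 4 of 5 measured genes were lower and 1 higher, with a median of -4.31 at percentile 0.81. The collagen gene COL4A2 was at least 268.5-fold lower, GATA6 at least 30.9-fold, APOA1 29.7-fold and DAB2 12.7-fold, whereas the retinol carrier RBP4 was 16.6-fold higher. This percentile was not kept in 3 of 9 settings: it was 39.2 without a filter, where the median over 16 genes was -0.22, 38.1 with the stricter filter and 3.0 with an offset of 1. In the trophectoderm list, 4 of 7 were lower and 3 neither (median -2.33). PTGS2, which is also on the inflammatory list, was 23.0-fold lower, GATA3 17.6-fold, GATA2 7.94-fold and HAND1 at least 6.17-fold. In the list of the primed epiblast, 1 of 5 was higher, 3 lower and 1 neither (median -1.49). POU3F1 was at least 15.6-fold higher there, and DNMT3A, FGF2 and FST were 2.86-fold, 2.67-fold and 2.37-fold lower. In the list of the naive state and LIF-STAT3 signalling, 4 of 5 were lower and 1 neither (median -2.34), with MYC at least 20.6-fold, NR5A2 at least 17.9-fold and JAK1 4.63-fold lower beside KLF4. Without a filter the medians moved toward 0, to -0.47 over 14 trophectoderm genes, -0.55 over 7 of the primed epiblast and -1.39 over 8 of the naive state.

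Among 9 epithelial genes, 2 were higher, 6 lower and 1 neither, with a median of -2.19 at percentile 22.4. CLDN7 was 12.4-fold higher and EPCAM at least 3.34-fold higher, while CLDN6 was 38.7-fold, MAL2 at least 13.9-fold and JUP 12.9-fold lower. CDH1, KRT18 and KRT19 were on the array but too dim to pass the filter. Their highest readings in the lines were 25.9, 3.62 and 1.30. The epithelial median was -0.20 without a filter (20 genes, 2 higher and 8 lower), -1.36 in pESK I alone and -3.02 in pESK II alone. The trunk patterning list held 7 measured genes, 4 of them higher, 2 lower and 1 neither, with a median of 1.26 at percentile 96.9. HOXA3 was 4.91-fold higher, HOXD8 2.76-fold and HOXA9 2.33-fold, while MEIS1 was 2.91-fold and HOXB7 2.24-fold lower. Of 6 endothelial genes, 4 were lower and 2 neither (median -1.90). ENG, which is also on the mesenchymal list, was 15.7-fold lower and ERG at least 12.5-fold. Without a filter the endothelial median was -0.71 over 13 genes. Of 5 neural genes, 1 was higher (GAP43, 9.64-fold), 2 were lower (NCAM1 by 20.4-fold and MAP2 by 10.7-fold) and 2 met neither rule (median -1.89). The neural median was -0.30 over 8 genes without a filter, -0.70 in pESK I alone and -3.58 in pESK II alone. In the haematopoietic list, HBB, a globin gene, was 5.11-fold higher and SPI1 met neither rule. HBE1, AHSP, ALAS2 and PTPRC were on the array but did not pass the filter. ALAS2 read at most 64.5 and the others at most 17.8 on any array. In the germ line list, KIT was 2.63-fold lower and GDF9 met neither rule. Under quantile normalization and median centring KIT did not pass the filter, and GDF9 alone differed by 0.19 and 0.22. Of the male-linked list (median -0.80), SRY did not pass under these scalings, and EIF1AY alone differed by 0.63 and 1.12.

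Of 12 TGF-beta and BMP genes, 1 was higher (INHBA, 4.44-fold), 6 were lower and 5 neither (median -1.17). ID3 was 66.8-fold lower, TGFB2 21.9-fold and ID1 11.6-fold; without a filter the median was -0.75 over 16 genes. Of 8 FGF and MAPK genes, 1 was higher (FGF13), 3 lower and 4 neither (median -1.04), with FGF7 at least 11.2-fold and ETV5 2.58-fold lower. Of 6 WNT genes, 2 were higher, 3 lower and 1 neither, with a median of -0.32. Under quantile normalization and median centring TCF7L2 also passed the filter, and the median over 7 genes was 0.31 and 0.32. LEF1 and TCF7L1, transcription factors of the pathway, were 13.1-fold and 2.72-fold higher, and the secreted proteins DKK3 and SFRP1 were 102-fold and 55.3-fold lower. Of 11 imprinted genes, 0 were higher, 6 lower and 5 neither (median -1.19 at percentile 5.925, outside the middle 95% in 4 of 9 settings), with PHLDA2 104-fold, NDN 11.2-fold, MEG3 at least 8.47-fold and PEG3 at least 6.11-fold lower. Of 12 chromatin genes, 4 were higher, 1 lower and 7 neither (median 0.65). EZH2, the methyltransferase of Polycomb complex PRC2, was 8.76-fold higher, the maintenance DNA methyltransferase DNMT1 3.24-fold and HDAC2 2.44-fold.

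**Figure D3:**
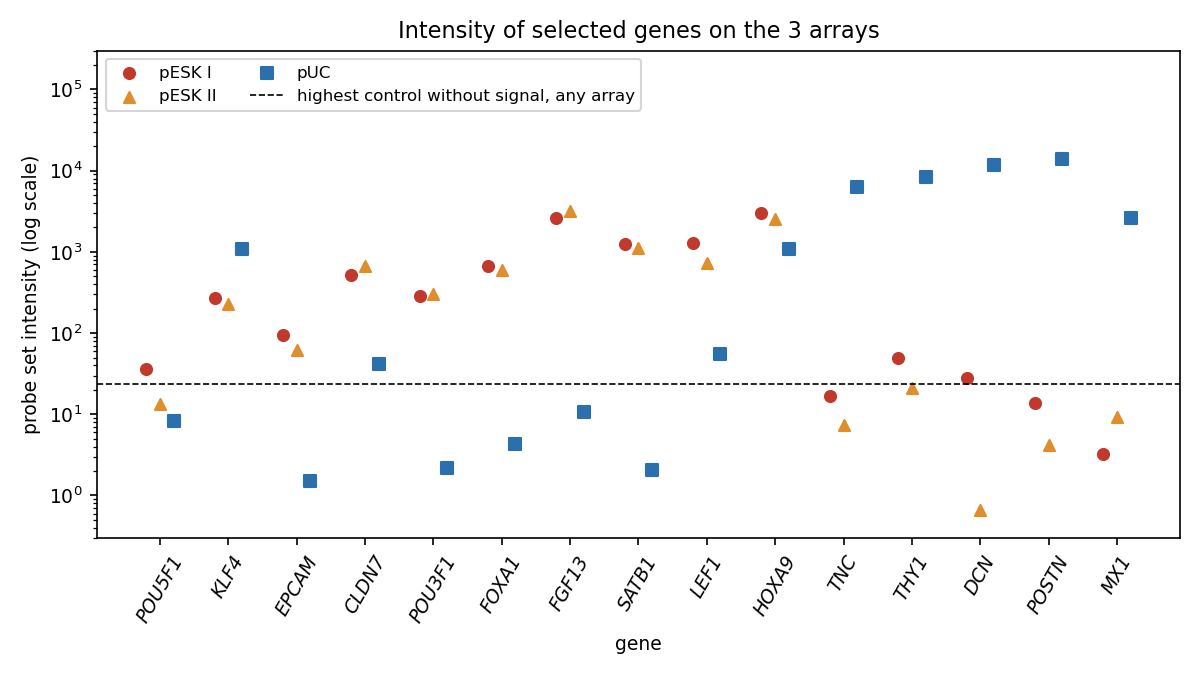
Probe set intensity on a logarithmic axis for 15 named genes on the 3 arrays, 1 point per array, with the highest control without signal of any array (23.5) as a dashed line. FGF13 reads 2628 and 3227 in the pESK lines against 10.5 in pUC, and POSTN reads 13.9 and 4.21 against 13813.

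Over all 5222 genes, 1081 (20.7%) were higher in both lines and 1213 (23.2%) lower, and 0 met the rule in opposite directions. At a 4-fold threshold, 323 were higher and 654 lower, and at 16-fold 27 and 205. Of the lower genes, 163 lay at or below the controls on both pESK arrays, and 42 of the higher genes did so in pUC. Across genes, which are not independent replicates, the differences of the 2 lines from pUC correlated with r = 0.978 (covariance 3.48), against 0.497 (covariance 0.0813) for simulated unchanged arrays sharing 1 control. Shared calls expected of unchanged arrays, with noise drawn from the differences between the lines, were 16.5 higher and 15.8 lower. Those expected of independent lists were 293 and 338. The single pUC array cannot be split, so part of the excess may come from it. The share of higher among called genes was 47.1%, 53.6% under quantile normalization (1224 higher, 1061 lower) and 68.3% under median centring (1795 higher, 833 lower). The median difference over all genes was 0.11 as deposited, 0.24 under quantile normalization and 0.67 under median centring, and the list medians stand relative to it.

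The second comparison sets the 2 lines against each other. TMEM98 was at least 28.6-fold higher in pESK I and STMN2, a neuronal microtubule regulator, at least 19.4-fold. LOC100511846 was at least 11.7-fold higher in pESK I, the matrix protein THBS1 8.14-fold, the Notch target HES1 6.77-fold and the immediate early gene IER2 5.92-fold. ACTC1, SLC1A1, FAM84A, DNAJB4, LOC396711 and VCAN were 5.66-fold, 5.15-fold, 5.01-fold, 4.87-fold, at least 3.85-fold and at least 2.91-fold higher in pESK I. In pESK II, ADSSL1 was 4.35-fold higher, PTGES, a prostaglandin E synthase, 4.11-fold, ST3GAL1 3.99-fold, EHF 2.98-fold and WAP at least 2.86-fold. AAED1, SCO2, NNAT, RNF113A, SELP, CXCL14 and KCNJ5 were higher in pESK II by 2.65-fold, 2.62-fold, 2.55-fold, 2.38-fold, at least 1.89-fold, at least 1.81-fold and at least 1.31-fold.

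Of the gene lists, 6 lay outside the middle 95% of random lists in this comparison. Smooth muscle genes had a median log2 difference, pESK I minus pESK II, of 0.49 (percentile 100), with DES 2.62-fold higher in pESK I as the 1 of 10 that met the rule. TGF-beta and BMP genes had a median of 0.41 (99.7), with ID3 and ID1 2.61-fold and 2.24-fold and TGFB3 at least 1.17-fold higher, the 3 of 12 that met the rule. Mesenchymal genes had a median of 0.24 (98.7), and 3 of 19 met the rule: SPARC, 2.90-fold higher in pESK I, DCN, below the controls in pESK II, and LUM, below them in both lines, so that LUM gives no direction. Epithelial genes had a median of 0.53 (98.0), with PERP 4.18-fold higher as the 1 of 9 that met the rule, but lay outside that range in only 3 of 7 settings (percentile 93.2 without a filter, 71.7 with the stricter filter). Chromatin genes had a median of 0.27 (99.5) and oxidative phosphorylation genes one of -0.31 (percentile 0), and in both lists 0 genes met the rule; NDUFA2 and NDUFA1 were 1.40-fold and 1.39-fold higher in pESK II.

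In all, 111 genes (2.13%) were higher in pESK I and 18 (0.345%) lower, and 97.53% of genes lay within 2-fold. Across genes, log2 values of the 2 lines correlated with Pearson's r = 0.985, against 0.595 and 0.584 for pESK I and pESK II with pUC. The split between higher and lower moved to 83 and 34 under quantile normalization and to 72 and 46 under median centring. Line, passage and way of isolation differ together and cannot be separated with 1 array each.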

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

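The tests of explanations in this part were chosen after the results had been seen, while the 2 other scalings they use had been fixed before the data were examined. Differences between the lines relative to pUC were not tested, since each line is 1 array.

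In 10 named genes the 2 lines lay on opposite sides of pUC, and 6 of these differed by a log2 of at least 1 between the lines. The log2 difference, pESK I minus pESK II, was 4.16 for STMN2, 2.40 for IER2 and 1.36 for EGR1, which were above pUC in pESK I and below it in pESK II. It was -1.37 for AAED1, -1.30 for SCO2 and -1.23 for RNF113A, which were below pUC in pESK I and above it in pESK II. The other 4 differed by less than 1: SPI1 by 0.61, SMARCA4 by 0.56, TPI1 by -0.31 and TYMS by -0.56. Under both quantile normalization and median centring, 4 of the 10 (STMN2, IER2, EGR1 and SCO2) lay on opposite sides, SCO2 in pESK I by only -0.01 under median centring, and 6 did not under at least 1 of them. Median centring shifts all genes of an array alike, so a gene close to pUC changes side by its closeness.

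Probe sets without a gene symbol carried signal outside the comparisons of named genes. Of 7027 such probe sets that passed the filter, 1311 were higher in both lines than in pUC and 1857 lower. The highest log2 difference among them was 8.35 in the line closer to pUC, with intensities of 7504 and 5807 in the pESK lines and 1.82 in pUC. The lowest was -9.08, with 13.0 and 7.21 in the lines, below the controls, and 15718.6 in pUC.

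More genes were higher in pESK I (111) than in pESK II (18). Of the 111, 78 (70.3%) were also lower in both lines than in pUC, against 23.2% of all genes. Of the 18, 6 were lower in both lines. Values near background do not account for the imbalance: with both pESK values above the controls, 84.0% of the called genes were still higher in pESK I. In the pESK I culture, RNA with the profile of the pUC array does not account for 17 genes. These exceeded pESK II by more than their whole pUC level. Under the cut-off used, the values also argue against such RNA for 73 of the other 94, taken as a set. Each value was taken as measured, with no allowance for noise between arrays, so none of the 73 is settled on its own. Those 73 would need more than 1.30% pUC RNA to reach the rule of size from pESK II. This cut-off is 2-fold above the lower quartile (0.651%) of the pESK I level, in percent of pUC, over 36 mesenchymal and matrix genes. Their median was 4.39%, with POSTN at most 0.160% and DCN 0.235%. For the remaining 21 the explanation stays open. Earlier forms of this test were dropped or left the question open. Cells with a profile unlike pUC, such as one low in POSTN and DCN, cannot be tested this way. Scaling stays open too: the share was 86.0% as deposited, 70.9% under quantile normalization and 61.0% under median centring, so part of the imbalance may come from it; passage and way of isolation, and RNA of the mouse feeder cells, were not tested and remain candidate explanations.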

How the results depend on the processing

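Counts over all probe sets and counts with both pESK values above the controls were chosen after seeing the data. Genes higher in both pESK lines numbered 1795 under median centring, 1833 with limma (adjusted p threshold 0.05; 1911 unadjusted), 323 at 4-fold and 2712 over all probe sets; genes lower in both numbered 654 at 4-fold and 3558 over all probe sets. The limma calls include all 1081 and 1213 genes called by size and treat the lines as replicates, with the lone pUC array assumed to vary like them. Genes higher in pESK I than in pESK II numbered 72 under median centring, 68 with the stricter filter, 196 and 35 with offsets of 1 and 64, 10 at 4-fold, 379 over all probe sets and 68 with both values above the controls. Genes lower in pESK I numbered 34 under quantile normalization, 46 under median centring, 68 without a filter, 8 with the stricter filter, 73 and 5 with offsets of 1 and 64, 0 at 4-fold and 80 over all probe sets. The other alternatives left these counts within 1.5 times. The mean log2 difference of KLF4 was -2.04, -1.52 under median centring and -1.87 with an offset of 64. Thresholds, filters and counts over all probe sets move a count by their construction; for the other changes the cause was not tested. The mesenchymal, matrix, smooth muscle, cell cycle and CDK inhibitor lists stayed outside the middle 95% of random lists in 9 of 9 settings against pUC, the interferon and inflammatory lists in 8 and the primitive endoderm list in 6. Between the lines, smooth muscle and oxidative phosphorylation did so in 7 of 7, TGF-beta, mesenchymal and chromatin in 6 and epithelial genes in 3. Leaving out a replicate was not possible with 1 array per group. Signal over background limits the 163 lower genes with only a bound in both lines and the 42 higher genes with only a bound in pUC. Lower genes with a bound in 1 line, such as DCN, are limited too and are not among the 163.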

Other observations

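The gene families and probe sets in this part were chosen after the data had been seen. Families were taken by gene symbol. Of 58 mitochondrial ribosomal protein genes, 31 were higher in both pESK lines than in pUC (51 under median centring) and 0 lower, with a median log2 difference of 1.19, and MRPS5 differed by 2.97 and MRPL1 by 2.17 in the line closer to pUC. Of 60 spliceosome and hnRNP genes, 35 were higher and 0 lower (median 1.31), with SNRPA1 at 2.43 and SNRPA at 2.38. Of 9 nucleoporin genes, 7 were higher and 0 lower (median 2.31), with NUP210 at 4.09, and all 6 genes of the chaperonin CCT were higher (median 1.41). Of 57 cytosolic ribosomal protein genes, 2 were higher and 1 lower (median 0.47), and 10 were higher under median centring. Most lie toward the top of the range of the arrays, which may limit the change they can show. This was not tested, so these counts do not show that they were unchanged. Of 33 proteasome genes, 6 were higher and 1 lower, and 3 were higher under quantile normalization and 25 under median centring. In each of these families the higher members also outnumbered the lower under quantile normalization and under median centring. Median centring shifts all genes of an array alike, here upward in pESK against pUC, so it gives little separate support. Against random lists, proteasome genes lay at percentile 93.5 and cytosolic ribosomal genes at 19.1, inside the middle 95%. The other families of this paragraph lay at 99.07 or above. Over all genes, 20.7% were higher in both lines.

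All 6 integrin genes were lower in both lines (median -5.70), as were 8 of 9 annexin and S100 genes (median -2.95), 7 of 8 cathepsin genes (median -2.99) and all 3 genes of IGF-binding proteins (median -4.66), and in each family the lower members outnumbered the higher under both other scalings. Among fatty-acid-binding proteins, FABP7, FABP5 and FABP3 were higher, with log2 differences of 4.58, 3.08 and 3.02 in pESK I, and FABP4 lower at -3.59.

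Of 64 probe sets whose names carry the array's prefix for reporter sequences, 5 were higher in both pESK lines than in pUC and 0 lower. The 5 read between 1794 and 11542 in pESK I and between 3440 and 10924 in pESK II, and 55.7 or less in pUC. At 1 of them pESK II read 9111 and pESK I 1794. The labels put lentiviral vectors in the pESK lines, and which sequences these probe sets read was not analysed here.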
